A study of Homo sapiens with 63 samples.

How the data were processed

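HEK293 cells, a human embryonic kidney line, were grown in log phase, kept without serum for 2 h, or kept without amino acids for 1 h in a salt solution with vitamins and serum, per the labels. Lysates made with cycloheximide, which holds ribosomes on mRNA, were spread over a gradient that was collected in numbered fractions. Poly(A)-selected RNA of fractions 3 to 22 was sequenced as stranded mRNA libraries, per the labels' protocols. Values therefore describe polyadenylated RNA only, and any histone mRNA without a poly(A) tail was not measured. The labels describe 63 samples, of which 60 are fractions (20 per condition) and 3 are lysates. There was 1 gradient per condition, so no difference has a replicate check and no p-value was computed. The labels do not say which end of the numbering holds the heavier material, so positions are given as lower- or higher-numbered fractions.

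Reads were quantified with kallisto 0.44.0 and sleuth 0.29.0 on the hg38 transcriptome, per the submitters' processing notes. The deposited signal is a table made by the authors with 1 value per gene symbol and fraction. Its name calls the values TPM, but the 60 columns sum to between 38696 and 67126017. Each fraction therefore carries a further scale from the authors that is not given in the sources used here, and values are called signal. Library depths are not given in the sources used here either, so no counting error was attached to any value. The table held 11075 rows counted as genes and 29 spike-in RNA sequences with ERCC names. A luciferase spike-in row was counted among the genes, so it stood in the fraction totals and outside the spike-in sums. It held 2.6% of the total of fraction 22 without serum and 2.1% without amino acids. The lowest mean of a gene over the 60 columns was 2.19, and the filter behind that floor is not stated in the sources used here. Symbols were matched to the GRCh38.p14 gene table, in which 11041 had an entry (11013 protein coding and 28 others) and 34 had none. Coordinates come from that table.

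The position of a gene was its mean fraction number, weighted by signal over fractions 3 to 22. A shift was the position in a starved gradient minus that in another gradient, minus the median of that difference over all tested genes. Positive shifts point to higher-numbered fractions relative to the median gene. A gene with a positive shift can still lie at a lower-numbered position than in the other gradient. Tested genes had a mean signal of 5 or more in each gradient and a value above 0 in at least 15 of the 20 fractions, which left 10890. Odd-numbered and even-numbered fractions were also analysed apart as the spread within a gradient. A gene met the size rule, which is not a test, with a shift of at least 1 fraction and at least 0.5 in the same direction in both odd and even fractions. The level of a gene was its signal summed over the fractions, per 1000000 of the gradient's total. Log2 ratios of levels used a pseudocount of 1, and genes needed a level of 5 on that scale in either gradient. A level difference met the size rule at 1 or more on the log2 scale with 0.5 or more in both odd and even fractions.

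Of the gene lists, 29 were written before the data were examined, and the 26 with at least 5 tested members were summarised. Mitochondrially encoded mRNAs, snoRNA host genes and long noncoding RNAs had too few members. A list's median was placed among 10000 random lists of the same size matched on mean signal, and the range quoted holds their central 95%. That percentile describes these libraries and is not a p-value. For each contrast, the genes named were the 6 largest shifts or level differences in each direction that met the size rule, with a mean signal of 10 or more in both gradients for shifts and a level of 10 or more in either gradient for levels, the most abundant and most extreme members of each list, and genes fixed in advance. For the log phase gradient, the 5 lowest and 5 highest positions were named. Any other gene named is said to be chosen after its values were seen.

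The contrasts, size rules, filters, lists, naming rule and most alternatives were fixed before the data were examined. Several steps differ from that design. The table used holds no lysate columns, so the planned lysate comparisons were replaced by levels summed over fractions. The odd and even fractions took the place of the planned second reading of the level rule, and mean signal took the place of lysate TPM in the naming rule. Weights and scalings of the fractions taken from the lysates were not run. The lysate libraries were not analysed here. The level ratios were centred on the median of all genes, which the design held only as an alternative, and this was decided after the medians had been seen. Uncentred counts over all genes stand beside the centred ones, but counts of list members past the level rule are given centred only. The direct comparison of levels between the starvations was added after seeing the data. Added alternatives chosen after seeing the data gave every fraction the same total, scaled fractions by their spike-in sum, or left out fractions 6 and 7.

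The remaining alternatives were other filters, pseudocounts, centrings, size rules and summaries of a profile, and leaving out each fraction number in turn. Calculations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9. The steps were tested on simulated data first. With the log phase gradient set against a simulated copy of 10890 genes, shifts of -3, -2, -1.5 and 1.5 fractions in 50 genes each gave medians of -3.007, -2.046, -1.478 and 1.517. The size rule called 100%, 100%, 94% and 94% of them, and 4 of 10690 unchanged genes. For levels over 8158 genes, 100 of 100 simulated 4-fold differences were called in each direction, with 0 calls among unchanged genes. In both simulations the noise was independent for each value, with no variation between gradients or in the scale of fractions. The calls among unchanged genes therefore do not give the rate of false calls between real gradients.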

Results

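Poly(A) RNA was measured across gradients of HEK293 lysates to show where each mRNA sedimented in growing, serum-starved and amino acid-starved cells. Each condition gave 20 fractions from 1 gradient, so none of the differences below has a replicate check. Signal summed over fractions was 391869519 in log phase, 164066525 without serum and 184290266 without amino acids, which were 0.419 and 0.47 of the log phase total. The log phase total peaked in fraction 18, which held 17.1% of it. Both starved gradients peaked in fraction 9, with 16.4% and 16.3% of their totals. The lowest total of any fraction was 38696, in fraction 6 of the log phase gradient. In log phase, fractions 8 to 12 held 12.8% of the total and fractions 18 to 22 held 43.7%. Without serum these shares were 45.7% and 22.4%, and without amino acids 54.9% and 14.6%. All these totals, ratios and shares carry the unknown scale that the authors gave each fraction. They cannot be read as measured amounts of RNA.

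**Figure D1:**
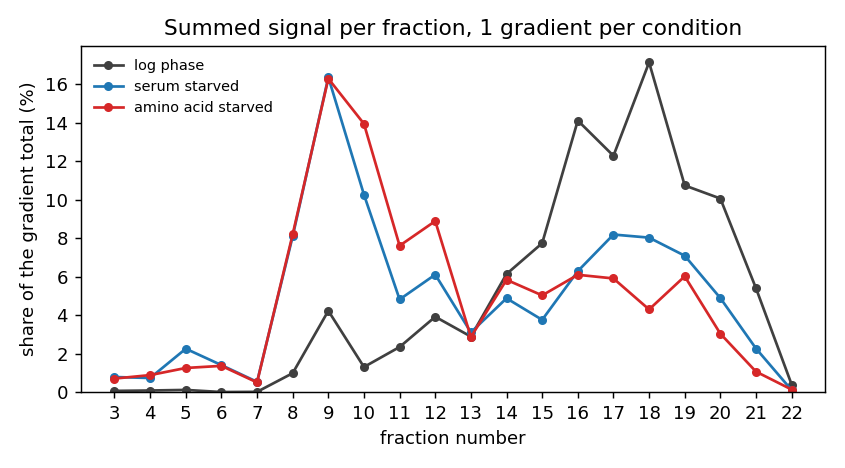
Share of each gradient's summed signal (percent) against fraction number, with 1 line per gradient and 1 point per fraction. The log phase line peaks at 17.1% in fraction 18, and the serum-starved and amino acid-starved lines peak at 16.4% and 16.3% in fraction 9. The shares carry the unknown scale that the authors gave each fraction and are not measured amounts of RNA.

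In log phase, heat shock chaperones had a median position of 18.74, glycolysis enzymes 18.43, cytosolic aminoacyl-tRNA synthetases 18.16, DNA replication and S phase genes 18.14, and proteasome subunits 17.98. Among genes with a mean signal of 10 or more, the highest positions belonged to PGK1, a glycolysis enzyme, at 19.58, PHGDH, the first enzyme of serine synthesis, at 19.50, ACO1 at 19.42, PARP1 at 19.36 and CAP1 at 19.33. At the other end, very short coding sequences had a median position of 14.95, polyamine and iron genes 15.03, replication-dependent histones 15.56, small ribosomal subunit proteins 15.65, uORF-regulated stress mRNAs 15.74 and large ribosomal subunit proteins 16.01. All of these medians lay outside the central range of matched random lists. ATF4 and DDIT3, stress transcription factors with upstream open reading frames, sat at 14.03 and 13.76. The lowest positions among them were those of CCL5 at 6.42, SEMA3E at 7.72, FBXO48 at 9.17, and of MTRNR2L8 at 11.22 and MTRNR2L1 at 11.30, near-copies of a mitochondrial rRNA gene whose values are uncertain for that reason. The median over all genes was 16.94, and 14.28 when every fraction was given the same total. Very long coding sequences, at 17.50, lay 0.56 above the median of all genes but 0.73 below it (-0.73) with equal totals. Equal totals set lists further apart relative to that median, with heat shock chaperones at 4.23, glycolysis enzymes at 3.86, small subunit proteins at -2.92 and large subunit proteins at -2.49. The lowest positions also moved, with SEMA3E at 3.81 with equal totals and at 12.39 without the outermost fractions.

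After serum starvation, the elongation factor EEF1A1 (chromosome 6, 73515750 to 73521032) had a shift of -5.23 fractions relative to the median of all genes, the lowest among genes with a mean signal of 10 or more in both gradients. BEST1, chosen after its values were seen and with a mean signal of 9.23 in log phase, was lower at -6.52. The poly(A)-binding protein PABPC1 followed at -4.81, the ribosome scaffold RACK1 at -4.73, SLC25A6 at -4.64, RPL5 at -4.62 and RPL4 at -4.57. From log2 signal EEF1A1 was at 0.10 and RPL4 at 0.08, and the other 4 lay between -0.19 and -0.03. The share of EEF1A1 signal in fractions 18 to 22 was 64.9% in log phase and 9.8% without serum, while its share in fractions 8 to 12 was 8.0% and 68.3%. Large ribosomal subunit proteins had a median shift of -3.01 (odd fractions -3.10, even -2.83), with 46 of 47 lower. Small subunit proteins had a median of -3.05, with 32 of 32 lower, among them RPS6 at -4.19. The other mRNAs with a 5′ terminal oligopyrimidine (TOP) tract had a median of -3.25, with 21 of 22 lower, such as EEF2 at -3.83 and TPT1 at -4.38 (-1.47 with equal totals). RPL41 (-0.26) and EIF3K (-0.80) did not meet the size rule, but stood at -1.30 and -1.67 with equal totals, and at -1.04 and -0.49 without fraction 9. RPL41 was at 0.03 without fraction 16. All 3 medians lay below those of all 10000 matched random lists, and 34 of the 50 genes of lowest shift at a mean signal of 10 or more were among these 101 mRNAs. The lists kept medians of -2.59 or lower with equal fraction totals. They did not keep them when positions were computed from log2 signal, a summary that flattens the profiles of abundant genes. There the large and small subunit lists reached 0.08 and 0.07 and the other TOP mRNAs -0.10, of which the last lay below all random lists and the others inside their range.

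**Figure D2:**
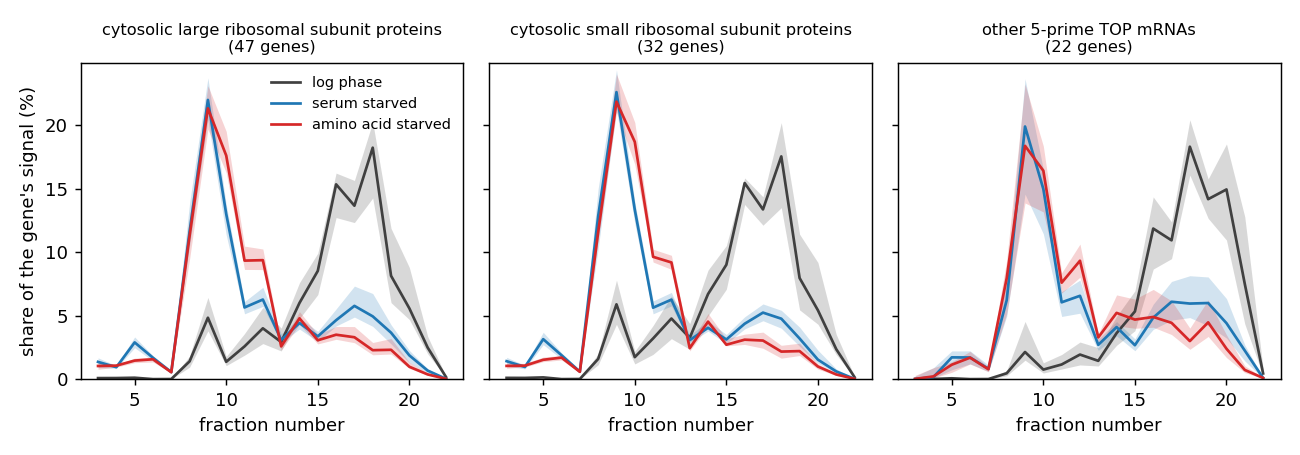
Share of a gene's signal (percent) against fraction number for large ribosomal subunit proteins (47 genes), small subunit proteins (32) and other 5′ TOP mRNAs (22), with the median over genes as a line and the interquartile range as a band for each gradient. In fractions 8 to 12 the median share of large subunit genes was 14.1% in log phase, 59.7% without serum and 70.2% without amino acids.

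Across all 10890 genes, 621 were higher and 1075 lower than the median without serum. Of the 621, only 209 lay at a higher-numbered position than in log phase before centring. Genes of highest shift at that signal were OTUB1, a deubiquitinase (chromosome 11, 63986438 to 63998412), at 2.55, NUBP1 at 2.52, EXOSC3, WBP4 and RBKS at 2.24, and ARF4 at 2.12 (0.90 with equal totals). Heat shock chaperones had a median of -0.69 (-1.13 with equal totals), with 6 of 16 lower and 0 higher, including HSPA8 at -3.35, while HSP90AA1 was at 0.72 (-0.65 with equal totals). Aminoacyl-tRNA synthetases had a median of -0.23 (-0.68 with equal totals), with 3 of 22 lower, including QARS at -3.69, and was at -0.35 without fraction 19 and -0.45 without fraction 20, while WARS was at 0.86 (-0.75 with equal totals). Immediate early genes had a median of -0.38, with 6 of 26 lower, including EGR1 at -2.44, JUND at -1.81 (-0.30 with equal totals) and FOS at -1.5, which was below the size rule without fraction 8 (-0.96) or 9 (-1.34). That median was 0.60 with equal totals, -0.06 without fraction 8 and -0.20 without fraction 9. Proteasome subunits had a median of 0.40, with 4 of 34 higher and 1 lower (PSMD7 2.06, PSMB4 -1.80), but 0.22 without fraction 19 and -0.86 with equal totals. Zinc finger genes of the C2H2 type had a median of -0.25, with 49 of 345 lower and 5 higher, including ZNF277 at -3.31, and 0.27 with equal totals. These 5 medians lay outside the range of matched random lists. GAPDH was at -3.57 and, with equal totals, at -6.57. The ferritin heavy chain FTH1 was at -2.99, but at -0.06 with equal totals and -0.26 with spike-in scaling. ATF4 was at -1.16, at 0.27 from log2 signal, and below the size rule without fraction 16 (-0.94), 18 (-0.92) or 19 (-0.94). Before centring, the median gene lay 1.35 fractions lower than in log phase (-1.35; odd -1.13, even -1.55), but higher by 1.49 with equal totals. With log2 signal 14 genes were higher and 54 lower, and without centring 1 and 7539.

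Without amino acids, the lowest shifts at that signal were those of RACK1 at -5.10, FTH1 (chromosome 11, 61964285 to 61967634), the iron storage protein, -5.02, EEF1A1 -4.99, PABPC1 -4.93, RPL5 -4.77 and BCDIN3D -4.63. From log2 signal FTH1 was at 0.18 and EEF1A1 at 0.14, and the other 4 lay between -0.22 and -0.04. EEF1A1 had 5.4% of its signal in fractions 18 to 22 and 73.8% in fractions 8 to 12. Large ribosomal subunit proteins had a median of -3.22 (odd -3.06, even -3.16), with 45 of 47 lower, small subunit proteins -3.08, with 32 of 32 lower, and other TOP mRNAs -3.35, with 21 of 22 lower. RPS6 was at -4.30, EEF2 at -3.62 and TPT1 at -3.94, while NACA was at -0.92 (-1.53 with equal totals) and RPL41 at 0.42 (-1.34 with equal totals, -0.30 without fraction 9). All 3 medians again lay below those of all random lists and at -2.78 or lower with equal totals, and 34 of the 50 lowest genes belonged to these lists. From log2 signal the medians were 0.13, 0.14 and -0.10, of which the last lay below all random lists and the others inside their range.

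Among 10890 genes, 745 were higher and 1043 lower without amino acids, against 13 and 71 from log2 signal, 1411 and 1708 with equal totals, and 1 and 9408 without centring. Of the 745, only 91 lay at a higher-numbered position than in log phase before centring. HIST1H1C, a linker histone, had the highest shift at 3.44 among genes with a mean signal of 10 or more in both gradients, before OTUB1 at 3.21, EXOSC3 at 2.87, NUBP1 at 2.82, ARF4 at 2.73 and PPP1R2 at 2.72. Replication-dependent histones had a median of 0.35 (2.01 with equal totals, 1.34 with spike-in scaling, 0.54 without fraction 18 or 19), with 3 of 16 higher and 1 lower (HIST3H2A -1.90, but 0.88 with equal totals). Heat shock chaperones had a median of -0.86 (-0.30 with spike-in scaling), with 7 of 16 lower, and HSPA8 was at -3.11. Aminoacyl-tRNA synthetases had a median of -0.48 (-0.93 with equal totals), with 4 of 22 lower, and QARS was at -3.38. C2H2 zinc finger genes had a median of -0.18, with 40 of 345 lower and 11 higher, which was 0.34 with equal totals and 0.02 with spike-in scaling, and -0.11, -0.08 and -0.07 without fractions 8, 18 and 19 in turn. These medians lay outside the range of random lists. GAPDH was at -3.88 (-6.82 with equal totals), and FTH1 at -1.62 with equal totals and -2.56 with spike-in scaling. BCDIN3D was at -1.95 without the outermost fractions and -1.45 with equal totals. Before centring, the median gene lay at -1.80 (odd -1.48, even -2.11), but at 1.67 with equal totals.

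**Figure D3:**
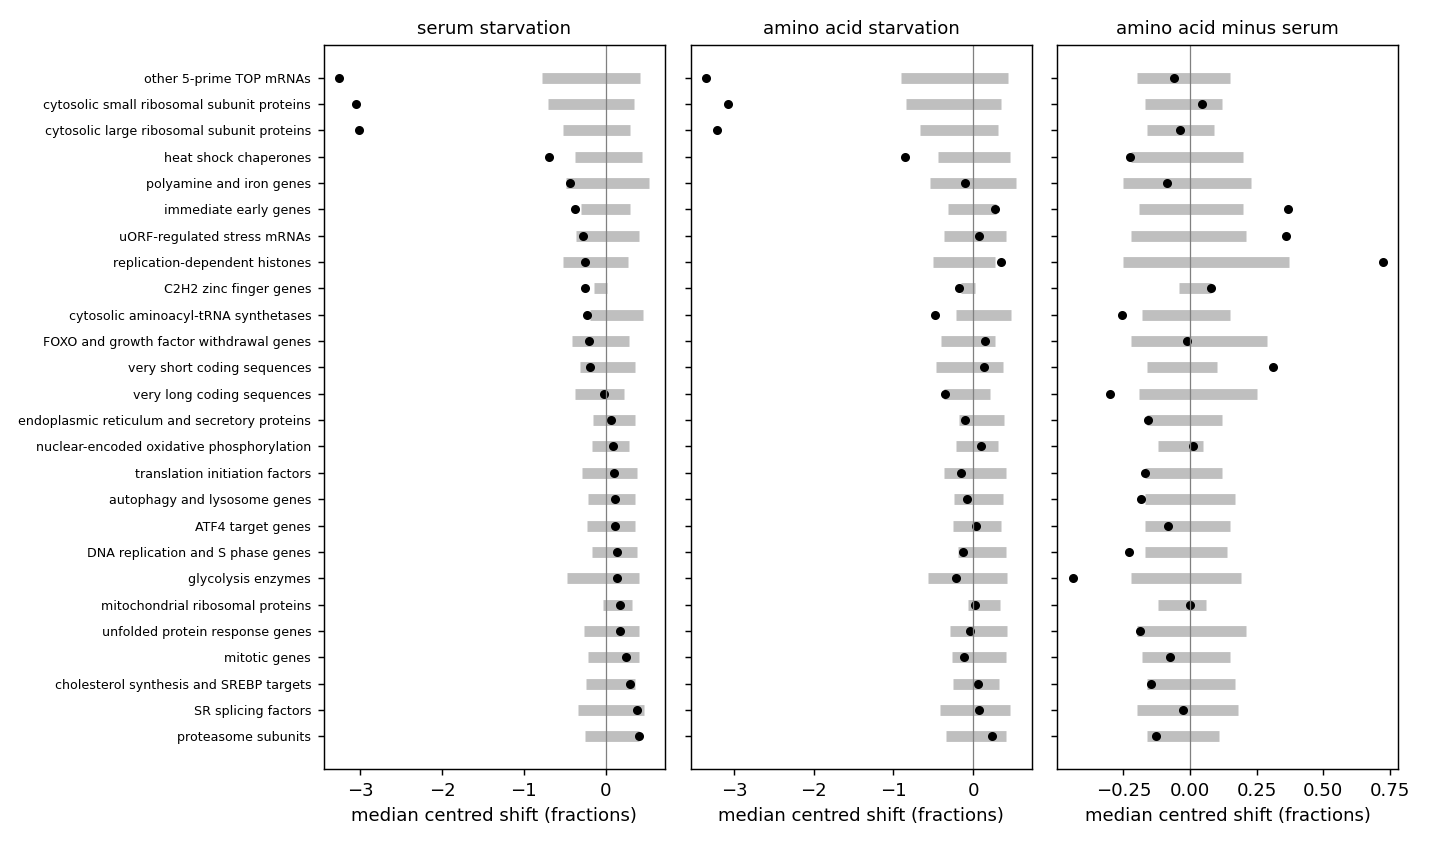
Median centred shift (fractions) of 26 gene lists in the 3 contrasts, as black points, with grey bars for the central 95% of 10000 matched random lists. The ribosomal protein and other TOP lists lie between -3.01 and -3.35 in the starvation panels; of the lists outside their grey bar, immediate early genes, proteasome subunits and zinc finger genes in the serum panel, zinc finger genes in the amino acid panel, and heat shock chaperones in the difference panel take the opposite sign with equal fraction totals.

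The shifts of the starvations had r = 0.841 across genes, which are not independent replicates, against 0.493 for simulated gradients without an effect that share the log phase control. Their covariance was 0.564, against 0.063 simulated. Shifts from odd fractions for serum and from even fractions for amino acids, in starved and log phase gradients alike, gave r = 0.78, and the reverse 0.631. The odd and even control fractions still came from the same log phase gradient. Genes lower in both numbered 722 (1.14 simulated, 103 for independent lists), and genes higher in both numbered 416 (14.87 simulated, 42.5 for independent lists). The simulated noise was drawn gene by gene from differences between odd and even fractions within a gradient. It holds no variation between gradients or in the scale of fractions. The simulated values may therefore understate the agreement that the shared control gives without an effect. Only EGR1 met the size rule in opposite directions, at -2.44 and 1.07, and the latter was below the rule without fraction 9 (0.97), 20 (0.73) or 21 (0.87). Before centring EGR1 was lower in both, at -3.79 and -0.73.

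EGR1 (chromosome 5, 138465479 to 138469303), an immediate early transcription factor induced by serum, lay further towards higher-numbered fractions without amino acids than without serum, by 3.52 fractions relative to the median gene (3.06 before centring). Its mean fraction was 16.63 in log phase, 12.84 without serum and 15.90 without amino acids. The other genes of highest difference with a mean signal of 10 or more in both gradients were CCDC122 (4.23, but 2.08 without fraction 3), ZNF177 (2.91), XPNPEP3 (2.48, but 1.60 without fraction 8, and outside the size rule at 2.02 without fraction 19), FAM156A (2.22) and LPAR6 (1.87). XPNPEP3 and LPAR6 were at 0.86 with equal totals. BEST1, below that signal without amino acids and chosen after its values were seen, was at 4.22. Immediate early genes had a median difference of 0.37 (-0.10 before centring), with 4 of 26 higher (EGR1, FOS at 1.85, PHLDA1 at 1.45, but 0.49 with equal totals, and BTG2) and 0 lower, and KLF10 was at -0.29. Histones, measured as polyadenylated RNA only, had a median of 0.72, with 6 of 16 higher, including HIST1H1C at 1.73. The uORF-regulated stress mRNAs had 0.36 (-0.11 before centring), with ATF4 at 0.97. SLC35A4 (1.13, but 0.72 with equal totals and 0.96 without fraction 10) was alone among these 16 past the rule. Very short coding sequences had a median of 0.31, with 0 of 38 past the rule, or -0.16 before centring, -0.03 when centred within 10 bins of starting position and 0.18 without fraction 21. Medians below 0 relative to all genes, with 0 members lower by the size rule, were those of glycolysis enzymes (-0.44, or -0.28 without fraction 21; LDHB -0.77), very long coding sequences (-0.30), aminoacyl-tRNA synthetases (-0.25, but -0.02 with equal totals and -0.06 without fraction 21), S phase genes (-0.23, but -0.01 with equal totals), autophagy and lysosome genes (-0.18, or -0.29 without fraction 18 or 19, with 2 of 27 higher) and endoplasmic reticulum and secretory proteins (-0.16, or -0.09 without fraction 19). The autophagy genes past the rule were BECN1 at 1.24 and MAP1LC3B, chosen after its values were seen, at 1.07, which was below the rule without fraction 9 (0.96), 10 (0.95), 20 (0.99) or 21 (0.95). The S phase median was -0.15, -0.37 and -0.04 without fractions 9, 19 and 21 in turn. Heat shock chaperones had -0.22, with DNAJB4 higher at 1.32 and 0 lower, but -0.40 in odd and 0.08 in even fractions, 0.27 with equal totals, 0.23 with spike-in scaling and -0.01 without fraction 21. These medians lay outside the range of random lists. Single genes of lowest difference at that signal were ESCO2 (-3.09, but outside the size rule without fraction 3, at -0.85, or 4, at -2.72), RAB3B (-2.15), FTH1 (-2.01), ZKSCAN1 (-1.95), CDK6 (-1.88, but -1.01 without fraction 9) and LPP (-1.86). The ferritin light chain FTL, chosen after its values were seen, was at -1.39. Ribosomal and other TOP lists had medians of -0.04, 0.05 and -0.06, inside the random range. In all, 219 genes were higher and 115 lower, against 38 and 844 without centring. ESCO2 turned to 0.30 without the outermost fractions, where RAB3B was at -0.75, and from log2 signal the immediate early median was -0.03 and the counts 5 and 16. The lower count was 80 without fraction 9 and 187 without fraction 17, and shifts from odd and from even fractions correlated across genes at 0.35.

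**Figure D4:**
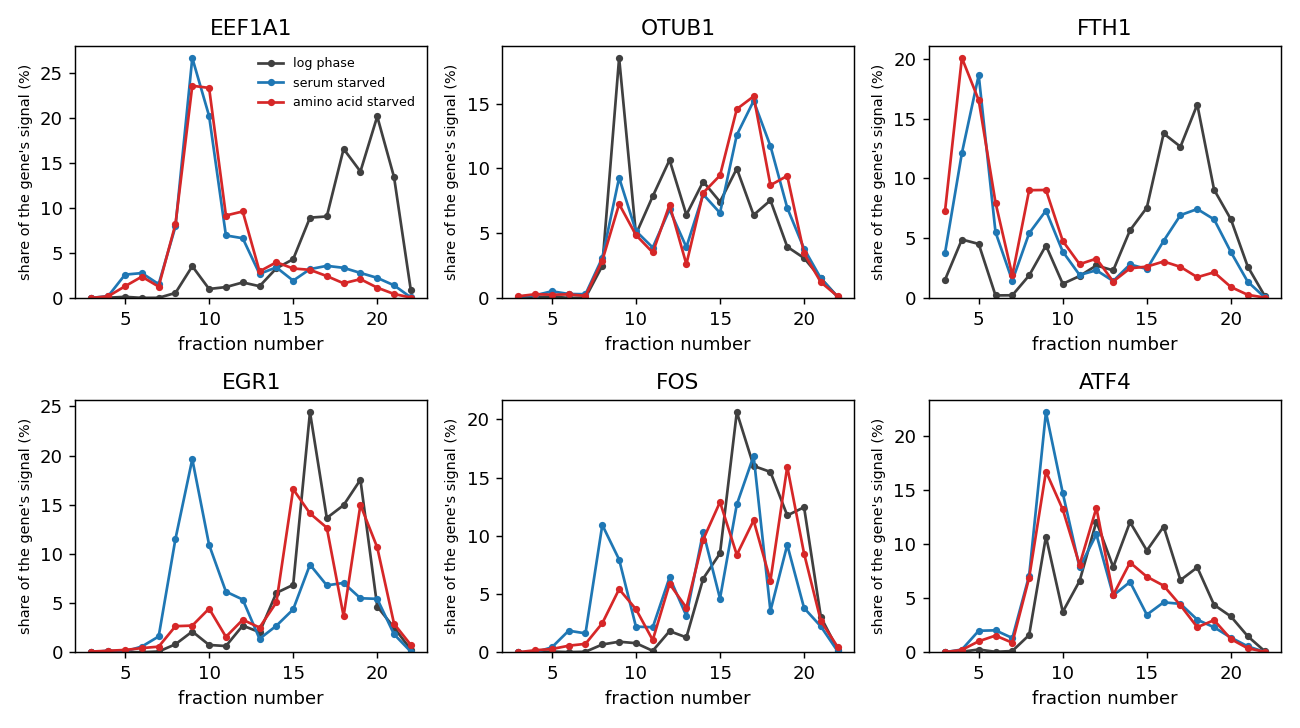
Share of a gene's signal (percent) against fraction number for EEF1A1, OTUB1, FTH1, EGR1, FOS and ATF4 in the 3 gradients, with 1 point per fraction. EEF1A1 has 64.9% of its signal in fractions 18 to 22 in log phase, 9.8% without serum and 5.4% without amino acids.

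After serum starvation, ID1 (chromosome 20, 31605289 to 31606510) and ID3, inhibitors of differentiation, had the lowest levels relative to log phase among genes with a level of 10 or more in either gradient. They stood at -3.22 and -2.36 on the log2 scale relative to the median gene, SMAD6 at -2.06, CYR61 at -1.96, CTGF at -1.83 and SHB at -1.52. Immediate early genes had a median of -0.29, with 4 of 16 lower and 0 higher. SR splicing factors (-0.54), heat shock chaperones (-0.40), translation initiation factors (-0.30) and mitotic genes (-0.30) were also below the range of random lists, with SR splicing factors at -0.24, heat shock chaperones at -0.19, initiation factors at -0.04 and mitotic genes at -0.03 with equal totals. Autophagy and lysosome genes had a median of 0.36, with 5 of 26 higher, including HEXA at 1.58, FOXO and growth factor withdrawal genes 0.38, unfolded protein response genes 0.39 and ATF4 targets 0.32, but these 4 medians were -0.08, -0.05, -0.05 and -0.11 without centring. The highest levels at that minimum were those of MTRNR2L1 (3.28), MTRNR2L6 (3.19), MTRNR2L4 (3.17), MTRNR2L8 (3.15), SPTLC3 (2.48) and IDS (1.94), and all 6 turned negative with equal totals, between -0.24 and -1.18. Of 8189 genes, 248 were higher and 74 lower. With a pseudocount of 5, CTGF was at -0.93, SMAD6 at -1.09, SHB at -1.23 and CYR61 at -1.41. The median gene had -0.43, and without centring on it 40 were higher and 733 lower.

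After amino acid starvation, CHAC1 (chromosome 15, 40953471 to 40956512), a glutathione-degrading enzyme and ATF4 target, had the highest level relative to log phase at 3.28. NUPR1 stood at 2.13, DDIT3 at 2.09, the cystine transporter SLC7A11 at 1.90, ATF4 at 1.77 and ASNS, asparagine synthetase, at 0.92 (0.32 without centring). ATF4 targets had a median of 0.98, with 12 of 28 higher and 0 lower, above all random lists, and of 0.39 without centring. Large and small ribosomal subunit proteins had medians of 1.04 and 1.06, with 25 of 47 and 21 of 32 higher, but 0.42 and 0.31 with equal totals. The lowest levels were those of LUC7L2 (-1.80), CALML4 and EIF4A3 (-1.74), NOL6 (-1.71), CHKA (-1.66) and NOP2 (-1.65). SR splicing factors had a median of -0.80 (-0.40 with equal totals), with 6 of 18 lower, mitotic genes -0.50 (0.01 with equal totals), translation initiation factors -0.49 (-0.09) and heat shock chaperones -0.46 (-0.02). MTRNR2L1 (3.04), MTRNR2L6 (3.00), MTRNR2L4 (2.94) and MTRNR2L8 (2.93) again turned negative with equal totals, between -0.32 and -0.55. With equal totals ATF4 was at 0.40, DDIT3 at 0.78, NUPR1 at 1.13, SLC7A11 at 1.14, LUC7L2 at -0.59, EIF4A3 at -0.01, CHKA at -0.78 and NOP2 at -1.05. With a pseudocount of 5, CHAC1 was at 2.18 and no longer highest, with MTRNR2L6 at 2.57. DDIT3 was then at 1.60, SLC7A11 at 1.14, LUC7L2 at -1.58, NOP2 at -1.56, CHKA at -1.32 and NOL6 at -1.14. Of 8190 genes, 407 were higher and 230 lower around a median of -0.59, and 43 and 1824 without centring. With equal totals 193 were higher and 87 lower, of which 127 were among the 407 and 25 among the 230.

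Set directly against each other, the starved gradients differed in level at few genes, with 14 of 7475 higher and 3 lower without amino acids. ID1 (3.28), CHAC1 (3.06), CYR61 (2.42), ID3 (2.08), the inhibitor of NF-kappa-B NFKBIA (1.21) and STC2 (1.12) were the highest with a level of 10 or more in either gradient. C10orf10 (-2.26), CLK4 (-1.23) and BEST1 (-1.75, chosen after its values were seen) were the lower ones. Immediate early genes had a median of 0.56, with 4 of 18 higher, and ATF4 targets 0.44, with 5 of 28 higher, both above all random lists. The former was 0.36 at levels of 20 or more and 0.35 without the level filter, and the latter 0.27 without centring. Large and small ribosomal subunit proteins also lay above all random lists, at 0.28 and 0.33, but at 0.01 for both with equal totals. So did uORF-regulated stress mRNAs (0.26, or 0.08 without centring) and very short coding sequences (0.22, or 0.03 with equal totals). With a pseudocount of 5, ID1 was at 2.71, CHAC1 at 1.95, CYR61 at 1.77, STC2 at 0.91, CLK4 at -0.74 and BEST1 at -0.78. Without centring, on a median of -0.17, the counts were 8 and 9.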

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

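The tests below were chosen after the results were seen, except that of high abundance.

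EGR1 was singled out because it alone met the size rule in opposite directions in the starvations, and its shifts, each centred on the median of its own contrast, differed by 3.51 fractions. Its shift without amino acids, 1.07, was below the rule without fraction 9 (0.97), 20 (0.73) or 21 (0.87), and before centring it was lower in both, at -3.79 and -0.73. The difference was not tested, with 1 gradient each. The sum of the 29 spike-in sequences with ERCC names, which the main comparisons do not use, varied between fractions. From highest to lowest it differed by 107.2-fold in log phase, 24.1-fold without serum and 26.8-fold without amino acids. The luciferase spike-in was not part of those sums. No explanation was tested for that spread.

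Ribosomal protein and other TOP mRNAs lay at lower-numbered fractions in both starvations, relative to the median gene and before centring. The scaling of the fractions would have to bring at least 1 list above -1 when totals are equal, but the median nearest 0 was -2.59. That test covers equal totals only, as the authors' scale is not known. Short coding sequences would have to shift with them, but those outside the lists had medians of -0.18 (SE 0.068, 36 genes) and 0.14 (SE 0.051). Abundance would have to move the 100 most abundant genes outside the lists, which had medians of 0.16 (SE 0.124) and 0.20 (SE 0.14). Each SE came from resampling genes and holds no variation between gradients. From log2 signal the ribosomal lists were at 0.07 to 0.14 and inside the range of random lists, while the other TOP mRNAs were at -0.10 in both starvations, below all random lists. No biological explanation was tested, and the starvations themselves stay open.

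Most genes lay at lower-numbered fractions in both starvations before centring. Without fractions 6 and 7, whose totals were low in log phase, the median nearest 0 was -1.26. Those fractions held 0.01% and 0.02% of the log phase total. They held 1.41% and 0.54% without serum, and 1.37% and 0.51% without amino acids. Leaving out so little signal could hardly move a median, so no conclusion is drawn from it. Scaling cannot be told apart from a change in the cells. Spike-in scaling left a median of -0.51 nearest 0, but equal totals gave 1.49 and 1.67, and those fix the mean of the whole gradient. The starvations themselves stay open and untested as a cause.

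Relative to the median gene, immediate early mRNAs lay at higher-numbered fractions without amino acids than without serum, by a median of 0.37, but the difference before centring was -0.10. With equal totals and with spike-in scaling the lower of the medians was 0.34, above the upper random limits of 0.21 and 0.20. Centred within 10 bins of starting position it was 0.37, above a limit of 0.15, which argues against a trend with starting position. Equal totals and spike-in sums do not account for the difference either. The authors' scale is not known, so other scalings stay open. The difference was not seen from log2 signal (-0.03). The difference in medium, which held serum in the amino acid starvation per the labels, stays open and untested.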

How the results depend on the processing

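Giving every fraction the same total, scaling by spike-in sums, leaving out fractions 6 and 7, and all alternatives for the direct comparison of levels were tests chosen after the data had been seen. Across 524 recomputed counts, medians and TOP list values, 428 stayed within their spread or within 1.5 times the count, 89 moved further and 7 reversed. A value is called reversed here if it took the opposite sign and was a list median outside its random range, a named gene that met the size rule, or the median gene shift before centring. Of 2977 recomputed list values, 2626, 310 and 41 fell into those classes, and of 3063 recomputed values for named genes 2183, 856 and 24. Many recomputed values left out a single fraction, namely 300 of the 524, 1440 of the 2977 and 1740 of the 3063. Of these, 299, 1427 and 1468 stayed, so the other alternatives changed results more often than the totals show. Values that began inside the random range or below the size rule also took the opposite sign. They numbered 34 for lists and 7 for genes with equal totals, 44 and 8 without centring, and 22 and 4 from log2 signal. With spike-in scaling they numbered 20 and 3, with centring in bins 17 and 0, and with the median fraction 11 and 0. Apart from leaving out single fractions, they numbered at most 6 and 0 in any other alternative. Among them, equal totals put glycolysis enzymes at -1.37, histones at 1.04, S phase genes at -0.80 and mitotic genes at -0.64 in shift without serum, and histones at -0.64 and glycolysis enzymes at 0.42 in level without amino acids. Unless the construction of an alternative gives it, the cause of a difference was not tested. Sequencing depth is not given in the sources used here, so the smallest detectable difference is unknown, and the scale the authors gave each fraction sets which genes count as high or low in it. Fraction weights and scalings from the lysates, and the lysate comparisons, were not run because the table used has no lysate columns. Mitochondrially encoded genes are absent from that table, so the total was rebuilt without ribosomal protein genes alone. Leaving out each fraction number in turn kept the direction of the median gene shift in each comparison and of the TOP lists in each starvation. It moved a single count by more than 1.5 times, that of genes lower without amino acids than without serum, between 80 (without fraction 9) and 187 (without fraction 17).

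Equal fraction totals, which fix the mean fraction of the whole gradient by construction, gave a median gene shift before centring of 1.49 without serum, 1.67 without amino acids and 0.13 between the starvations. Genes of higher shift then numbered 1297 and 1411 in the starvations, with 1708 lower without amino acids and 316 lower between them. Shifts that reversed there were those of immediate early genes (0.60), proteasome subunits (-0.86) and zinc finger genes (0.27) without serum, zinc finger genes (0.34) and HIST3H2A (0.88) without amino acids, and heat shock chaperones between the starvations (0.27). In log phase the median gene lay at 14.28, and very long coding sequences at -0.73 relative to all genes. Higher levels numbered 160 without serum and 193 without amino acids, with 87 lower in the latter. Reversed levels without serum were those of proteasome subunits (0.17), S phase genes (0.12), histones (-0.39), MTRNR2L1 (-0.26), MTRNR2L6 (-0.26), MTRNR2L4 (-0.42), MTRNR2L8 (-0.39), SPTLC3 (-0.24) and IDS (-1.18). Without amino acids they were uORF-regulated stress mRNAs (-0.01), proteasome subunits (0.19), mitotic genes (0.01), S phase genes (0.20), MTRNR2L1 (-0.40), MTRNR2L6 (-0.32), MTRNR2L4 (-0.51) and MTRNR2L8 (-0.55). Between the starvations they were proteasome subunits (0.04) and mitotic genes (0.06). Spike-in scaling gave a median gene shift of -0.51 without serum and -0.88 without amino acids, and a log phase median of 16.94. It reversed FTL without serum (0.14), zinc finger genes without amino acids (0.02) and heat shock chaperones between the starvations (0.23). Levels then counted 160 higher and 39 lower genes without serum, and 203 and 119 without amino acids.

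Positions from log2 signal left 14 genes higher and 54 lower without serum, 13 and 71 without amino acids, and 5 and 16 between the starvations. This summary narrows the spread of shifts by construction, to an SD of 0.28 without serum and 0.31 without amino acids against 0.81 and 0.83. The large and small subunit proteins and other TOP mRNAs had 0.08, 0.07 and -0.10 without serum, and 0.13, 0.14 and -0.10 without amino acids. Other reversals without serum were immediate early genes (0.07), EEF1A1 (0.10), RPL4 (0.08), TPT1 (0.17), ATF4 (0.27), FTH1 (0.51) and FTL (0.46). Without amino acids FTH1 (0.18), EEF1A1 (0.14), TPT1 (0.25) and FTL (0.14) reversed, and the median gene was at -1.22. Between the starvations the median gene was at -0.09, and aminoacyl-tRNA synthetases (0.01), immediate early genes (-0.03), glycolysis enzymes (0.03), heat shock chaperones (0.05) and S phase genes (0.01) reversed. The median fraction in place of the mean gave 1821 lower genes and a median gene of -0.75 without serum, and 832 higher, 404 lower and -0.82 between the starvations, with 17.38 in log phase. The TOP lists then had -5.27, -5.57 and -5.61 without serum, and -4.71, -4.79 and -4.91 without amino acids.

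Without centring, 1 gene was higher and 7539 lower without serum, 1 and 9408 without amino acids, and 38 and 844 between the starvations, as the median of all genes is then part of each shift. The TOP lists had -4.36, -4.40 and -4.60 without serum and -5.02, -4.88 and -5.15 without amino acids. Proteasome subunits (-0.95) reversed without serum, histones (-1.45) and EGR1 (-0.73) without amino acids, and uORF-regulated stress mRNAs (-0.11), immediate early genes (-0.10) and very short coding sequences (-0.16) between the starvations. Uncentred levels gave 40 higher and 733 lower genes without serum, 43 and 1824 without amino acids, and 8 and 9 between the starvations. They reversed ATF4 targets (-0.11), FOXO and growth factor withdrawal genes (-0.05), unfolded protein response genes (-0.05), autophagy and lysosome genes (-0.08) and secretory proteins (-0.09) without serum. Without amino acids, oxidative phosphorylation (-0.22), uORF-regulated stress mRNAs (-0.13), unfolded protein response genes (-0.11), very short coding sequences (-0.06) and secretory proteins (-0.35) reversed. With totals lacking ribosomal protein genes and no centring, lower genes numbered 225, 615 and 6 in the respective comparisons.

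A size rule of 0.5 fraction gave 1584 higher and 1783 lower genes without serum, 1587 and 1779 without amino acids, and 766 and 470 between the starvations. At 2 fractions these were 15 and 286, 49 and 266, and 9 and 3. Centring within 10 bins of starting position gave 73 higher genes between the starvations and -0.03 for very short coding sequences. A mean signal of 20 gave 133 higher and 51 lower genes there, and a log phase median of 16.96. Adding 1 to each fraction gave 76 lower genes, and so did dropping the 2 outermost fractions at each end, where ESCO2 was at 0.30 and the log phase median at 16.69. A level pseudocount of 5 gave 99 higher and 39 lower genes without serum, 154 higher without amino acids, and 5 and 1 between the starvations. With a pseudocount of 0.1, 5 genes were lower between them. Levels of 20 or more gave 148, 270 and 6 higher genes, and 1 lower and zinc finger genes at 0.05 between the starvations. Without the level filter, 377 genes were lower without amino acids, and FOXO and growth factor withdrawal genes were at 0.02 between the starvations.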

Other observations

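The level comparison of the starvations, the equal totals and the genes singled out here were chosen after the values were seen.

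Relative to the median gene, ribosomal protein mRNAs held higher levels without serum, with medians of 0.75 for the large and 0.77 for the small subunit. These were 0.31 and 0.34 without centring and 0.34 for both with equal totals. When centred, 2 of 47 and 2 of 32 members passed the size rule. Other TOP mRNAs had 0.65 and, without amino acids, 0.71, but 0.22 and 0.12 without centring and 0.36 in both with spike-in scaling. Replication-dependent histones had a median level of 0.74 without serum over 6 measured members, but -0.39 with equal totals. Without amino acids, oxidative phosphorylation genes had a median of 0.37 (-0.22 without centring), very short coding sequences 0.53 (-0.06), unfolded protein response genes 0.49 (-0.11), uORF-regulated stress mRNAs 0.47 (-0.13) and secretory proteins 0.24 (-0.35). Proteasome subunits had -0.13 without serum and -0.24 without amino acids, and S phase genes -0.24 and -0.29, all of them positive with equal totals. In the direct comparison, mRNAs of SR splicing factors had a median of -0.27, S phase genes -0.14 and cholesterol synthesis genes -0.19, or -0.10, -0.02 and -0.10 with equal totals.

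Several lists had shifts inside the random range in all 3 contrasts. Mitochondrial ribosomal proteins had medians of 0.17 without serum and 0.02 without amino acids, oxidative phosphorylation genes 0.09 and 0.10, ATF4 targets 0.11 and 0.04, FOXO and growth factor withdrawal genes -0.21 and 0.15, and cholesterol synthesis genes 0.30 and 0.06. Unfolded protein response genes had 0.17 and -0.04, mitotic genes 0.24 and -0.11, SR splicing factors 0.38 and 0.07, translation initiation factors 0.10 and -0.15, and polyamine and iron genes -0.44 and -0.10. With equal totals mitochondrial ribosomal proteins were at -0.36 and -0.32, oxidative phosphorylation genes at -0.58 and -0.46, initiation factors at -0.44 and -0.61, and cholesterol synthesis genes at -0.14 and -0.50. FOXO genes were then at 0.28, mitotic genes at -0.64 and SR splicing factors at -0.08 without serum. Of 30 initiation factors, 6 were higher and 4 lower without serum, and 7 and 4 without amino acids. They ranged from -1.99 to 1.69 and from -2.22 to 2.68, where the highest was EIF4E.

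BEST1, whose annotated span (chromosome 11, 61949821 to 61965515) overlaps that of FTH1, had a difference of 4.22 fractions between the starvations where FTH1 had -2.01. Reads shared between overlapping genes were not examined.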
